A study of Mus musculus with 10 samples.

How the data were processed

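Glomeruli of 10 mice were isolated after perfusion of the heart with magnetic beads, and total RNA of each mouse was labelled with biotin and hybridised to 1 mouse expression array, per the labels and the design text of the series. The values analysed are log2 expression values deposited by the authors, which the submitters' processing notes name as RMA (robust multi-array average, a method that corrects background, normalizes quantiles between arrays and summarises the probes of a probe set). The version of RMA and its settings are not given in the sources used here. Scanner files were not used here, so background correction and probe summaries could not be changed. RMA makes the distributions of arrays alike and compresses changes of weakly expressed genes, so log2 changes near the lower end of the scale understate true differences.

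All 10 columns of the table were assigned to a mouse by its title in the labels, and 0 columns belonged to other samples. Genotypes came from the labels, and replicate numbers only name mice, in order of accession. Mutants and wild types were described as littermates, but litters are not given in the sources used here, so no pairing was fitted. Of 45101 probe sets, 64 Affymetrix controls were left out and 45037 were tested. The platform annotation gave exactly 1 gene for 34945 of them, several for 932 and none listed for 9160. Of the single-gene probe sets, 34741 matched a gene of the RefSeq table of assembly GRCm38.p6 by gene number, and 0 symbols needed an update. That table served for names, chromosomes and the order of genes, and no coordinates are printed because the data name no genome build. Each gene was represented by its probe set with the highest mean over all 10 arrays, which left 18193 genes.

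Genotypes were compared with limma (version 3.58.1, R version 4.3.3), using a linear model per probe set and moderated variances, with the mutant minus wild-type difference as the coefficient and no covariates. Two-sided p-values were adjusted over all 45037 probe sets by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a call. Every adjusted p of a gene comes from this limma fit unless the sentence names another setting, such as a mouse left out or gene means. Wt1 was also tested by an exact permutation test over all arrangements of 5 and 5 mice. In total 20 gene lists (cell types, pathways and processes) were tested with limma's camera on 1 probe set per gene, with a preset inter-gene correlation of 0.01 and adjustment over the lists, and again with the correlation estimated from the data and with fry. A further list of sex-linked genes checked the stated sex. The share of called genes on chromosome 2 and within 30 Mb of Wt1 was tested with two-sided Fisher exact tests. Test, gene lists, named-gene rule and most alternatives were fixed before the data were examined.

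Genes named in the text are Wt1, the 12 largest rises and the 12 largest falls among called genes whose genotypes did not overlap, up to 4 genes of each list with the smallest p, a fixed set of podocyte genes (Nphs1, Podxl, Synpo, Plce1, Scel, Sulf1, Vegfa, Col4a3 and Cdkn1c, with some others not reported here), and up to 10 called genes within 30 Mb of Wt1. Other called members of a list, Itga4, the genes from Cep250 to Rab5if and the retinoid and Hedgehog genes were named after their values were seen.

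The limma step was tested on simulated data with the real means and residual spreads of 45037 probe sets, 200 of them changed. For a change of 0.5 on the log2 scale 54.7% were recovered, for a change of 1 it was 91.4% and for a change of 2 it was 98.7%, with 4.37%, 4.66% and 5.53% of calls false. No probe set was called in 5 simulated sets without change. In 20 simulations of 18193 independent genes a list shifted by 0.3 was found in 100% of runs, with 1 false call over the 18 lists that share no gene with it. These list simulations hold no correlation between genes, so they say nothing of the preset correlation itself.

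Alternatives covered centring or quantile normalization of the deposited values, filters on low signal, other variance models, array weights, stricter thresholds, removal of probe sets that can match several transcripts, gene means, the mice whose animal numbers lie close together (wild types 2 to 4 and mutants 1 to 4) with and without their 2 runs of neighbouring numbers as a block, and each mouse left out in turn. A tubule score (the mean of the proximal and distal tubule lists per array) was added as a covariate after seeing the data, as was a chromosome 2 test that leaves aside a run of called neighbours. Figures were drawn with matplotlib (version 3.10.9) in Python (version 3.11.15).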

Results

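Glomeruli, the filtering units of the kidney, were profiled from 10 male mice aged 27 days. Of these, 5 carried 1 copy of the R394W allele of Wt1 (Wt1 +/R394W) and 5 were wild-type littermates (Wt1 +/+). Wt1 encodes a zinc finger transcription factor of podocytes, the epithelial cells that form the slit diaphragm of the filter, and the R394W change is a recurrent cause of Denys-Drash syndrome in patients. All mice came from 4 generations of backcrossing to FVB/N. The submitters described the mutants as having little albuminuria and no mesangial lesions under the light microscope, so the comparison asks which transcripts differ while lesions are not yet seen. Each mouse gave 1 array with 45101 probe sets, and the number of arrays limits the precision. Array medians lay within 0.0817 of each other on the log2 scale, and correlations between arrays over all probe sets ran from 0.985 to 0.997. No pair of arrays held identical values. The second principal component of the values ran from -29.56 to -9.35 in wild types and from 12.59 to 34.28 in mutants. A change below is the mutant mean minus the wild-type mean in log2 units, with its standard error (SE) and n = 5 mice per genotype.

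The transcript of Wt1 itself did not pass the test over all probe sets. Its only single-gene probe set (1425995_s_at, chromosome 2) read 11.30 ± 0.17 (SD, n = 5) in wild-type and 11.63 ± 0.16 (SD, n = 5) in mutant glomeruli. The change of 0.33 ± 0.10 (SE) had an adjusted p of 0.244 over all probe sets. An exact permutation test of this single value gave a two-sided p of 0.0159, where 0.00794 is the smallest p that 5 mice against 5 allow. A missense allele need not alter the transcript level, so this value does not check the genotype labels.

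Mutant glomeruli lost most of the signal of Scel and Sulf1. Scel, which encodes sciellin, fell by 3.56 ± 0.21 (SE) on the log2 scale (1422837_at, chromosome 14, adjusted p = 3.50e-05), an 11.8-fold difference, from 9.02 ± 0.48 (SD, n = 5) to 5.45 ± 0.27 (SD, n = 5). Sulf1, a sulfatase that removes sulfate groups from extracellular heparan sulfate, fell by 3.34 ± 0.26 (SE) on the log2 scale (1438200_at, chromosome 1, adjusted p = 9.89e-05), a 10.1-fold difference, from 10.30 ± 0.20 (SD, n = 5) to 6.96 ± 0.65 (SD, n = 5). The gene with the largest rise was Cyp26a1, which encodes an enzyme that degrades retinoic acid. It went from 6.64 ± 0.50 (SD, n = 5) to 9.99 ± 0.63 (SD, n = 5), a rise of 3.35 ± 0.31 (SE) with an adjusted p of 0.000275 (1419430_at, chromosome 19). In all 3 genes every mutant lay apart from every wild-type mouse. Of the other probe sets of these genes, 1 of 2 for Sulf1 was called in the same direction and the other one for Scel, with a low mean signal of 4.38, was not called.

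Other genes rose by smaller amounts. Col14a1, a collagen, rose by 2.48 ± 0.39 (SE), Frzb, a secreted Wnt antagonist, by 2.31 ± 0.34 (SE), and Dcn, the small proteoglycan decorin, by 1.83 ± 0.16 (SE). Cntnap2 (2.49 ± 0.18 SE) and Cadm1 (2.29 ± 0.16 SE), both cell adhesion molecules, rose as well, as did Perp, a desmosome-associated membrane protein (2.19 ± 0.18 SE). The splicing factor Rbfox1 rose by 2.14 ± 0.14 (SE), Calhm5 by 2.56 ± 0.41 (SE) and Parm1 by 2.18 ± 0.26 (SE). Adjusted p-values of these 9 rises were at most 0.0139. Ccbe1 (2.11 ± 0.42 SE, adjusted p = 0.0443) and Ccdc68 (1.89 ± 0.38 SE, adjusted p = 0.0489) completed the 12 largest rises. Both calls held only without wild type 2 or mutant 2 when 1 mouse was left out, with adjusted p up to 0.131 and 0.136 otherwise. Other probe sets were called in the same direction for Col14a1 (2 of 2), Frzb (1 of 1), Parm1 (1 of 1), Cadm1 (2 of 3) and Rbfox1 (2 of 3). None was called for Cntnap2 (0 of 2), Dcn (0 of 1, change -0.03) or Ccbe1 (0 of 3, at 1.88, -0.14 and 0.06). The Ccbe1 probe set at 1.88 had a mean signal of 6.04 and an adjusted p of 0.100. The others of Cntnap2, Dcn and Ccbe1 had low mean signals of 3.74 to 4.71, so they say little of a change.

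Among the falls, Cyp2s1, a cytochrome P450, dropped by 2.44 ± 0.19 (SE) and Pcsk6, a proprotein convertase, by 2.09 ± 0.15 (SE). Cdon, a cell-surface co-receptor of Hedgehog ligands, fell by 2.07 ± 0.13 (SE), and Efemp1, a fibulin of the extracellular matrix, fell 4.01-fold (SE 0.23 on the log2 scale). Snx31 fell by 1.98 ± 0.25 (SE), Shisa3 fell by 1.95 ± 0.18 (SE), and Fxyd6, a regulator of the sodium pump, fell by 1.93 ± 0.17 (SE). Gm266 fell by 1.72 ± 0.28 (SE), Aifm3 fell by 1.69 ± 0.11 (SE) and Mgat4a, a glycosyltransferase that branches N-glycans, fell by 1.63 ± 0.11 (SE). Adjusted p-values of these 10 falls were at most 0.0150. Shisa3, Aifm3 and Mgat4a each had 1 other probe set, called in the same direction. Those of Cdon (-0.10, mean signal 4.86) and Gm266 (-0.42, mean signal 5.77) were not called.

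**Figure D1:**
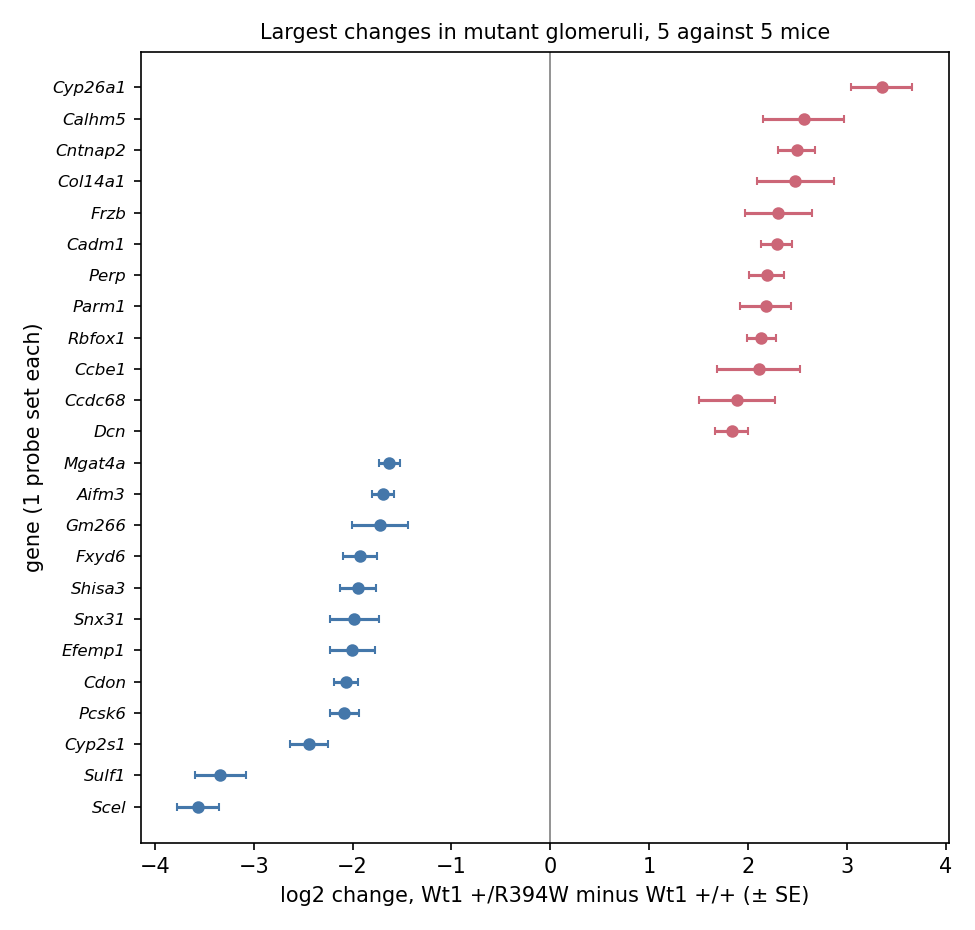
Log2 change (mutant minus wild type, bars show the SE, n = 5 mice per genotype) of the 12 genes that rose most and the 12 that fell most among genes past the threshold with separate groups. Cyp26a1 stands at 3.35 and Scel at -3.56.

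Over all transcripts, 384 of 45037 probe sets differed between the genotypes at an adjusted p under 0.05, with 176 higher and 208 lower in the mutants. Of these, 129 changed at least 2-fold, 71 upward and 58 downward. With 1 probe set per gene, 230 of 18193 genes passed, 103 higher and 127 lower, and in 225 of them the genotypes did not overlap. Groups were separate in 668 genes in all, or 3.67% of those measured, where chance gives 0.794%. Among the 35 called probe sets that name no single gene, 1441971_at (2.15 ± 0.20 SE) and 1455722_at (1.91 ± 0.12 SE) rose most, while 1430338_at (-1.55 ± 0.11 SE) and 1441491_at (-1.54 ± 0.15 SE) fell most. Leaving out wild type 1 lowered the total to 242 (105 higher, 137 lower, 150 genes), and leaving out wild type 4 lowered it to 216 (78 higher, 138 lower, 133 genes). With only wild types 2 to 4 and mutants 1 to 4, whose animal numbers lie close together, 110 passed (58 higher, 52 lower, 68 genes). The number of higher probe sets was also 106 without wild type 3, 112 without mutant 2 and 98 without mutant 3.

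Most podocyte structure genes did not pass the test. Of 35 measured genes, 3 fell and none rose: Scel, Plce1 and Thsd7a. Scel and Plce1 were reported from this model in the literature, so their falls, and their part in any shift of this list, are not independent evidence of a direction. Plce1, a phospholipase C whose loss causes early nephrotic syndrome, fell by 0.74 ± 0.11 (SE) on the log2 scale (1452398_at, chromosome 19, adjusted p = 0.00865). Thsd7a, a podocyte membrane protein, fell by 0.70 ± 0.13 (SE) on the log2 scale (adjusted p = 0.0314), a call that held without mutant 2, 3 or 4 and was lost without any other mouse (adjusted p up to 0.0819). Nphs1, the slit diaphragm protein nephrin, changed by -0.08 ± 0.08 (SE, adjusted p = 0.820), Podxl, which encodes podocalyxin, by -0.01 ± 0.06 (SE, adjusted p = 0.981) and Synpo, which encodes synaptopodin, by -0.24 ± 0.09 (SE, adjusted p = 0.429). Adjusted over the list alone, 1 gene was higher and 10 were lower. The list as a whole was shifted downward with the preset correlation (camera, adjusted p = 7.4e-05) and not with an estimated correlation (adjusted p = 0.751). Its median change was -0.09, and its mean per array lay between 11.15 and 11.34 in the mutants and between 11.44 and 11.55 in the wild types.

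**Figure D2:**
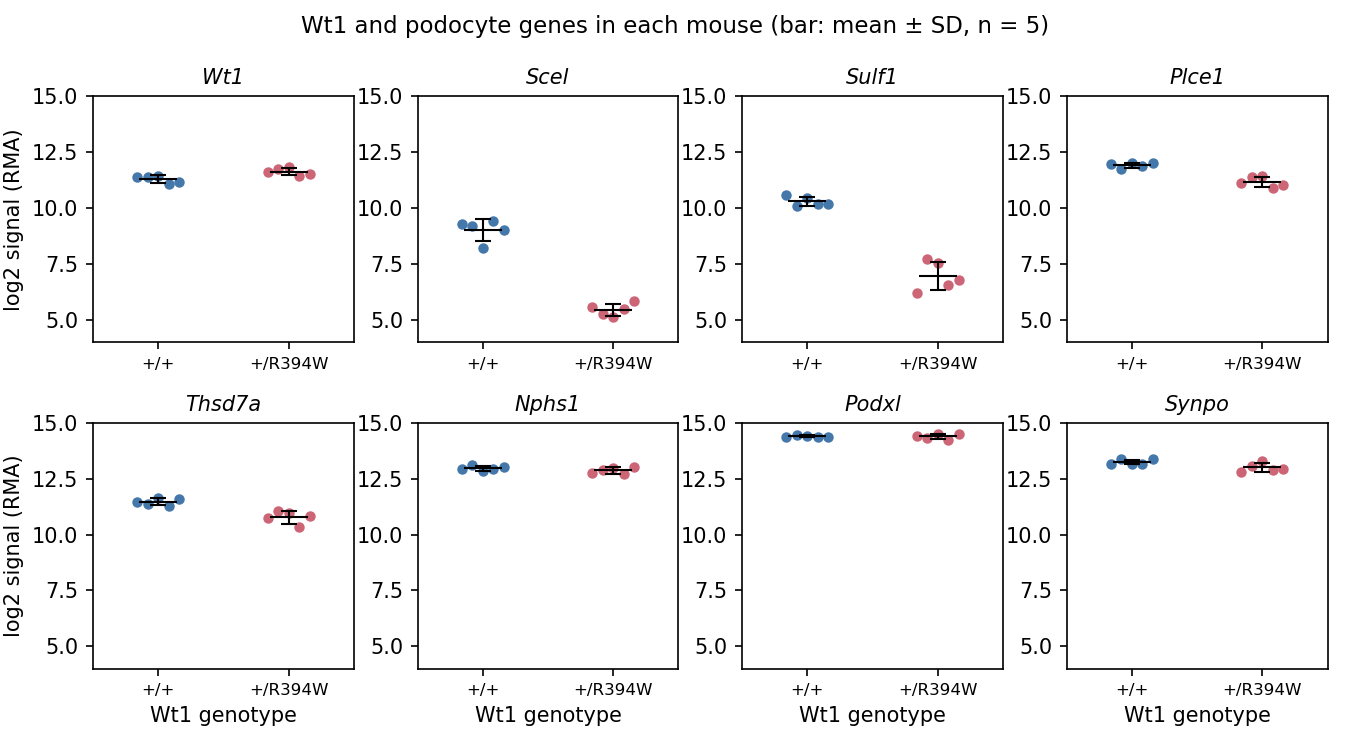
Log2 signal (vertical axis) of Wt1 and 7 podocyte genes in each of 5 wild-type (+/+) and 5 mutant (+/R394W) mice, with the mean and SD as black bars. Scel (-3.56) and Sulf1 (-3.34) change by more than the spread between mice, and Nphs1 (-0.08) and Podxl (-0.01) differ by less than the spread between mice.

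None of the 16 measured podocyte regulators passed. Foxd1 changed by -0.48 ± 0.14 (SE), Foxc1 by -0.20 ± 0.06 (SE) and the cell cycle inhibitor Cdkn1c by 0.26 ± 0.08 (SE), with adjusted p-values of 0.229, 0.283 and 0.253. With p adjusted over the list alone, 2 were higher and 2 lower, and the list was not shifted (camera, adjusted p = 0.208). Of 29 measured genes reported as WT1 targets, with 1 probe set per gene, 3 fell (Scel, Sulf1 and Plce1) and none rose. That list was drawn up from the literature, in which Scel, Sulf1 and Plce1 were reported from this model, so its count is not independent evidence of a direction. Adjusted over the list alone, which is not independent evidence either, 4 were higher and 6 were lower. The podocyte growth factor Vegfa (-0.31 ± 0.09 SE, adjusted p = 0.232), Bmp7 (0.66 ± 0.14 SE, adjusted p = 0.0545) and Col4a3 (-0.25 ± 0.13 SE, adjusted p = 0.629) did not pass by the probe set with the highest mean. Of the 2 other probe sets of Bmp7, 1 was called upward (1.04 ± 0.20 SE, adjusted p = 0.0395, mean signal 8.37). The remaining one was not called (0.67 ± 0.15 SE, adjusted p = 0.0704). The called probe set of Bmp7 does not enter the count of this list. The list shift was downward with the preset correlation (camera, adjusted p = 0.0362) and not called with an estimated correlation (adjusted p = 0.751). It was also lost without wild type 1 (adjusted p = 0.0618), wild type 2 (0.184), mutant 1 (0.0767) or mutant 4 (0.113), without probe sets that can match several transcripts (0.0705), and with a tubule score as a covariate, chosen after seeing the data (0.0893).

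Matrix genes moved in both directions. Of 29 measured genes of fibrosis and matrix remodelling, 4 rose: Dcn, the matricellular glycoprotein gene Tnc (1.20 ± 0.11 SE, adjusted p = 0.000395), the gelatinase gene Mmp2 (0.57 ± 0.10 SE, adjusted p = 0.0213) and the fibrillar collagen gene Col5a1 (0.44 ± 0.08 SE, adjusted p = 0.0252). The 2 that fell were Col1a2, a chain of type I collagen, by 1.55 ± 0.11 (SE, adjusted p = 5.98e-05), and Postn, which encodes periostin, by 0.95 ± 0.19 (SE, adjusted p = 0.0469). When 1 mouse was left out, the Mmp2 call was lost without wild type 1, 3 or 4 or mutant 2 or 4 (adjusted p up to 0.0679), the Col5a1 call without wild type 1, 3 or 4 or mutant 3, 4 or 5 (up to 0.0779), and the Postn call without any mouse except wild type 2 (up to 0.117). There were 12 higher and 2 lower genes adjusted over the list alone. The list was shifted upward with the preset correlation (camera, adjusted p = 1e-05) and not with an estimated correlation (adjusted p = 0.751). Of 24 basement membrane genes, only Lama1, a laminin chain, passed (0.96 ± 0.18 SE, adjusted p = 0.0362), and that call was lost without any 1 mouse except wild type 2 or mutant 3 (adjusted p up to 0.106). Frem2 (0.51 ± 0.11 SE), Agrn (-0.21 ± 0.06 SE) and Fras1 (-0.43 ± 0.13 SE) did not. Adjusted over the list alone, 2 were higher and 2 lower, and the list was not shifted (camera, adjusted p = 0.978).

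Of 21 genes of heparan sulfate synthesis and editing, Sulf1 fell and the sulfotransferase gene Hs6st2 rose by 0.85 ± 0.17 (SE, adjusted p = 0.0470), the latter lost without any 1 mouse except wild type 3 or mutant 1 (adjusted p up to 0.137). Sulf1 was reported from this model in the literature, so its fall in this list is not independent evidence. The second extracellular sulfatase gene, Sulf2, changed by -0.76 ± 0.18 (SE, adjusted p = 0.0996). Adjusted over the list alone, 1 was higher and 2 lower, and the list was not shifted (camera, adjusted p = 0.132). In the list of 21 VEGF and angiopoietin genes, Angpt2 rose by 0.39 ± 0.08 (SE, adjusted p = 0.0481) and the chemokine gene Cxcl12 fell by 0.97 ± 0.19 (SE, adjusted p = 0.0421), although the Cxcl12 values of the genotypes overlapped. Neither of the 2 other probe sets of Cxcl12 was called, at -0.55 (mean signal 8.15, adjusted p = 0.241) and -0.01 (mean signal 7.06, adjusted p = 0.978). The Angpt2 call held only without wild type 2 (adjusted p up to 0.124 otherwise) and the Cxcl12 call only without wild type 3 or mutant 2 (up to 0.116 otherwise). There were 6 higher and 4 lower genes adjusted over the list alone, and the list was not shifted (camera, adjusted p = 0.781). Of 33 Wnt and Notch genes, only the Notch ligand gene Jag1 passed (0.67 ± 0.12 SE, adjusted p = 0.0240), a call lost without any 1 mouse except wild type 2, wild type 4 or mutant 4 (adjusted p up to 0.0691). Adjusted over that list alone, 2 were higher and 3 lower, with no shift of the list (camera, adjusted p = 0.440).

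Few markers of other cell types passed the test. Among 24 endothelial markers only Sost passed, with a rise of 1.61 ± 0.31 (SE, adjusted p = 0.0395) that was lost without any 1 mouse except wild type 2, mutant 1 or mutant 2 (adjusted p up to 0.112). Nos3 changed by -0.37 ± 0.08 (SE, adjusted p = 0.0863) and Flt1 by -0.25 ± 0.08 (SE, adjusted p = 0.265). Adjusted over the list alone, 1 was higher and 3 lower. The list had a median change of -0.09 and was called downward with the preset correlation (camera, adjusted p = 0.0148), not with an estimated correlation (adjusted p = 0.751). It lost its call without wild type 2 (adjusted p = 0.0755), mutant 1 (0.0883) or mutant 5 (0.0975). No gene passed among 19 mesangial and smooth muscle markers (Acta2 0.89 ± 0.27 SE, Tagln 0.77 ± 0.28 SE), 12 parietal epithelial markers (Ncam1 -0.48 ± 0.11 SE), 22 proximal tubule markers or 21 distal nephron markers. None of these 4 lists was shifted (camera, adjusted p = 0.720, 0.781, 0.173 and 0.945). Adjusted over each list alone, 2 mesangial markers were higher and 1 lower, and 2 parietal markers were lower. Amounts of tubule differed widely between preparations in both genotypes. The mean of the proximal tubule list ran from 6.86 (wild type 5) to 9.34 (wild type 4) in wild types and from 6.96 (mutant 5) to 10.38 (mutant 4) in mutants. That list was called upward without wild type 1 (adjusted p = 0.0304), wild type 4 (0.0125) or mutant 5 (7.5e-05), and also with only wild types 2 to 4 and mutants 1 to 4 (0.00117, or 0.00445 with their runs of animal numbers as a block), and the distal list without mutant 5 (0.0281). These calls used the preset correlation, and over all 10 mice the adjusted p with an estimated correlation was 0.953 for the proximal and 0.990 for the distal list.

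Blood cell markers were lower at 1 gene in each list. The macrophage receptor gene Csf1r fell by 0.99 ± 0.17 (SE, adjusted p = 0.0220) among 24 leukocyte markers, which were not shifted as a list (camera, adjusted p = 0.781). The mitochondrial iron carrier gene Slc25a37 fell by 0.59 ± 0.12 (SE, adjusted p = 0.0436) among 6 erythroid markers, with wild type 5 (9.76) above the other wild types (9.13 to 9.29). The Csf1r call was lost without wild type 3, 4 or 5 or mutant 1, 4 or 5 (adjusted p up to 0.0619), and the Slc25a37 call held only without wild type 2, wild type 5 or mutant 3 (up to 0.102 otherwise). Adjusted over each list alone, 1 leukocyte and 2 erythroid markers were lower. The erythroid list was called downward with the preset correlation (camera, adjusted p = 0.0312), not with an estimated correlation (adjusted p = 0.751), and its call was lost without wild type 3 (adjusted p = 0.0626), wild type 5 (0.0975), mutant 1 (0.0767), mutant 4 (0.0812) or mutant 5 (0.0517). The erythroid call was also lost with array weights (adjusted p = 0.0808), without probe sets that can match several transcripts (0.123), with the tubule score as a covariate chosen after seeing the data (0.0583), and with only wild types 2 to 4 and mutants 1 to 4 (0.179, or 0.145 with their runs of animal numbers as a block).

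No cell cycle gene passed, although 30 of 31 measured genes had a positive change (Ccne2 0.70 ± 0.32 SE, Rrm2 0.74 ± 0.36 SE, Cdk1 0.49 ± 0.25 SE). The exception was Ccnd2 (-0.36 ± 0.10 SE, adjusted p = 0.170). The list was called upward with the preset correlation (camera, adjusted p = 0.00337), not with an estimated correlation (adjusted p = 0.953), and the call was lost without wild type 2 (adjusted p = 0.121), mutant 4 (0.113) or mutant 5 (0.338). Likewise, 24 of 26 mitochondrial respiration genes had a positive change with none past the threshold (Sdhc 0.18 ± 0.07 SE, Ndufa4 0.13 ± 0.06 SE). That list was called upward with the preset correlation (camera, adjusted p = 0.00230), not with an estimated correlation (adjusted p = 0.751), and lost its call without wild type 5 (adjusted p = 0.0556) or mutant 4 (0.0812), and with only wild types 2 to 4 and mutants 1 to 4 and their runs of animal numbers as a block (0.0567). No gene passed among 33 injury and inflammation genes (Ctsl -0.35 ± 0.11 SE, Plaur -0.22 ± 0.09 SE), 23 immediate early genes (Egr2 0.25 ± 0.08 SE) or 22 endoplasmic reticulum stress genes (Calr -0.18 ± 0.13 SE), and these lists were not shifted (camera, adjusted p = 0.781, 0.945 and 0.132). The endoplasmic reticulum stress list was called downward without wild type 3 (adjusted p = 0.000129) or mutant 5 (0.00482), and with array weights over all 10 mice (0.00221), all with the preset correlation, against an adjusted p = 0.953 over all 10 mice with an estimated correlation. Adjusted over each of these 5 lists alone, 0 genes passed, with limma giving 4215 probe sets at an unadjusted p under 0.05 over the whole array. In 3 lists the camera direction differed in sign from the median: parietal markers (median 0.06, mean 0.02, test downward), VEGF and angiopoietin genes (median -0.00, mean 0.06, test upward) and Wnt and Notch genes (median 0.01, mean -0.02, test downward). In all, 7 of 20 lists passed with the preset correlation, 0 with an estimated correlation and 0 with fry's test of a shared direction. The preset count was 4 without wild type 2, 4 without mutant 1 and 3 without mutant 4. Fry's mixed test asks for changes in either direction. It passed for some lists without a shift, such as heparan sulfate (adjusted p = 4.9e-10), Wnt and Notch (7.1e-08) and VEGF and angiopoietin genes (9.9e-06). It did not pass for others, such as cell cycle (0.422), injury and inflammation (0.367) and proximal tubule (0.548). All 10 arrays had low Xist (5.95 in wild types, 5.98 in mutants) with Eif2s3y at 9.17 and 9.42, matching the stated male sex.

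Because Wt1 lies on chromosome 2, a stretch of that chromosome from the strain in which the allele was made can accompany it through a backcross, and the share of called genes there was tested. Chromosome 2 held 30 of the 230 called genes (13.0%) against 7.76% of the genes tested, an odds ratio of 1.80 (95% interval 1.18 to 2.66, two-sided Fisher exact p = 0.00580). Adjusted over 20 chromosomes the p was 0.116. Within 30 Mb of Wt1 lay 10 called genes of 446 tested, an odds ratio of 1.81 (95% interval 0.85 to 3.43, two-sided Fisher exact p = 0.0815). They included Cd59a, a complement regulator, which fell by 1.21 ± 0.08 (SE, adjusted p = 3.50e-05), Rassf2, which fell by 1.26 ± 0.16 (SE), Ankrd63, which fell by 1.55 ± 0.20 (SE), Fmn1, which fell by 0.74 ± 0.12 (SE), and Fam171b, which fell by 0.88 ± 0.15 (SE). Frzb, Scg5 (1.64 ± 0.26 SE), Fbln7 (0.91 ± 0.14 SE), Ndufaf1 (0.58 ± 0.07 SE) and Aqr (0.31 ± 0.06 SE) rose. The Fam171b call was lost without wild type 1 or 4 or mutant 1, 4 or 5 (adjusted p up to 0.0554), and the Aqr call held only without mutant 1 (up to 0.0763 otherwise). The excess on chromosome 2 was no longer significant without wild type 3 (odds ratio 1.51), mutant 4 (1.63) or mutant 5 (1.47), was higher without wild type 1 (2.64), and leaving aside the genes from Cep250 to Rab5if, a run of 21 neighbours chosen after seeing the data, it was 1.46 (95% interval 0.908 to 2.24, two-sided Fisher exact p = 0.0982). Nor was it significant at an adjusted p under 0.01 (1.66) or with a 2-fold minimum (1.49).

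**Figure D3:**
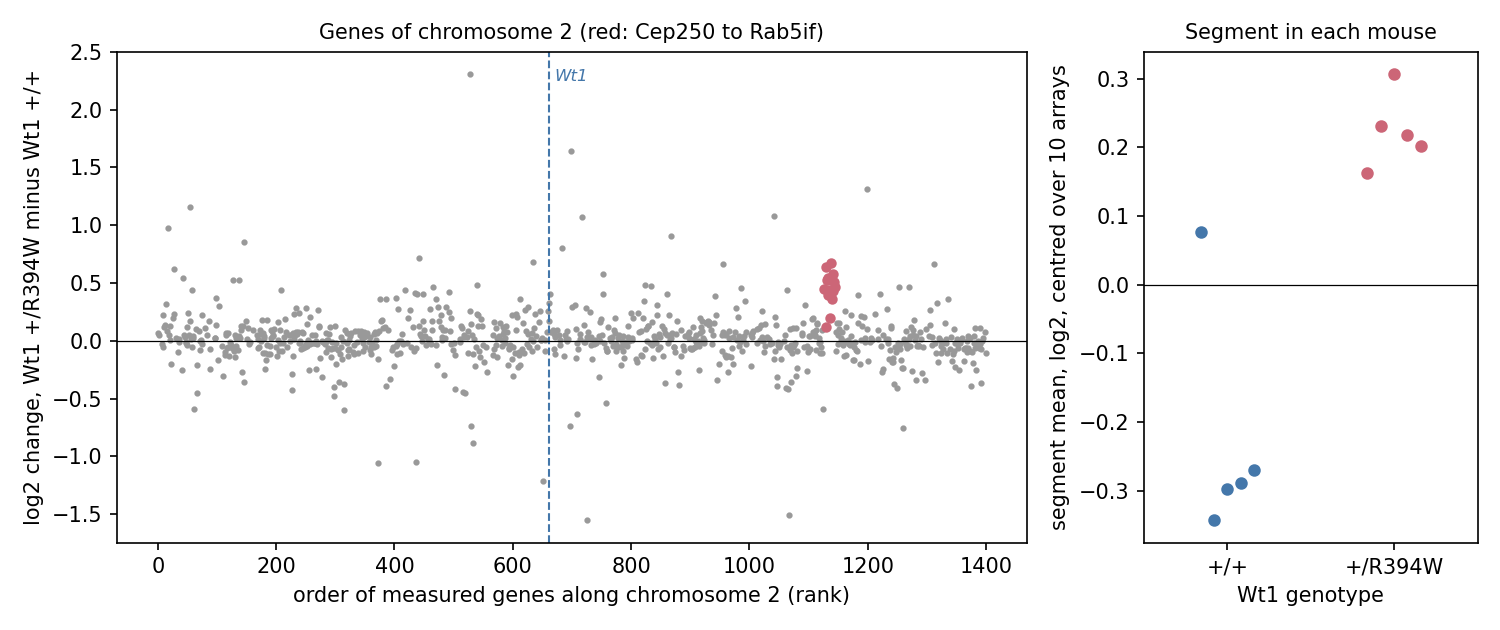
Left, log2 change (mutant minus wild type) of chromosome 2 genes with a mean signal above the median, in gene order with Wt1 as a dashed line and the genes from Cep250 to Rab5if, a run chosen after the values were seen, in red. Right, mean log2 signal of those red genes in each mouse after centring over the 10 arrays, from 0.16 to 0.31 in mutants and from -0.34 to 0.08 in wild types.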

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

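The tests with a tubule covariate, of podocyte number, of neighbouring genes and of copy gain were chosen only after the result was seen, and the copy-gain test replaced a first version that used the genes on which the run was found.

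The number of probe sets that differed between the genotypes, 384, can be set against other splits of the same 10 arrays into 5 and 5. Of 100 splits drawn from 126 possible ones, 1 gave as many, the real one, and the highest other split gave 10. This makes chance assignment of mice unlikely without excluding it. Not all splits were drawn, and mice were treated as exchangeable although litters are not given. Sequence from the donor strain around Wt1 as the whole cause is argued against by the share of called genes on chromosome 2, 13.0435% with an exact upper 95% limit of 18.1%, although this speaks only of effects on genes of that chromosome, and within 30 Mb of Wt1 an odds ratio of 1.81 (95% interval 0.85 to 3.43) leaves such an effect open. For the called genes, different amounts of tubule are argued against by the median ratio of changes with and without a tubule score as covariate, 1.003 (quartiles 0.982 to 1.03). The score itself differed little between the genotypes (mutant minus wild type 0.244, exact permutation test, two-sided p = 0.627). A ratio near 1 was therefore likely for genes called because their genotypes lay apart, and it says nothing of genes that were not called. For the called genes as a set, a sequence variant under the probes of 1 probe set is argued against. Of their other probe sets with a mean above the median signal, 96.0% moved the same way (121 of 126, exact lower 95% limit 91.0%), with weaker probe sets left out. Only 30 of the 230 called genes lie on chromosome 2, so this share cannot speak for the called genes near Wt1 by themselves. Genes called only by a probe set without the highest mean, such as Itga4, were left out.

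Lower Scel, Sulf1 and Plce1 could come from fewer podocytes in the mutant preparations. That would lower podocyte genes alike, and the median change of the podocyte structure list was -0.0872 (quartiles -0.326 to 0.0271), above the fall of Plce1 (-0.74), the smallest of the 3. This bears only on a loss large enough to give the whole fall of Plce1. A smaller loss was not tested. The list, which holds Scel and Plce1, had a lower mean in every mutant (11.15 to 11.34) than in any wild type (11.44 to 11.55). An effect of the mutant protein on Scel, Sulf1 and Plce1 stays open as a hypothesis, as does an effect of linked donor sequence on genes elsewhere.

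On chromosome 2, 6 of 21 measured genes from Cep250 to Rab5if were called, all higher in mutants (Cep250 0.52, Cpne1 0.64, Nfs1 0.52, Scand1 0.42, Epb41l1 0.67 and Myl9 0.58, with SE 0.09, 0.10, 0.10, 0.08, 0.11 and 0.11). Of the 15 with a mean above the median signal, all 15 had a positive change (median 0.449, against 0.0268 and 0.0258 in the 15 genes before and after), and 12 had an unadjusted p under 0.01. Runs of 15 neighbouring genes without any gene of this segment held at most 5 (highest median change of such a run 0.403). The run was picked for its high values, and the window was as long as its 15 genes. No distribution of the highest run under chance was drawn, so this comparison cannot decide about a chance cluster of unrelated calls. A gain of copies of this segment and a donor-strain difference in expression cannot be told apart here, since both could raise these genes: the 26 other probe sets of these genes with a mean above the median signal had a median change of 0.328 (quartiles 0.0331 to 0.437), where log2 of 3/2 is 0.585, but they measure the genes on which the run was found. Wild type 1 lay apart from the other wild types, with a mean centred level of 0.0767 where they ran from -0.343 to -0.270, and mutants from 0.163 to 0.307, and without it, a choice made after its value was seen, the median of 0.449 became 0.542. Calls of Nfs1 and Scand1 were held in only 1 of the 10 fits that left out 1 mouse (without wild type 1), that of Myl9 in 2 (without wild type 1 or mutant 2), and that of Cep250 was lost without wild type 3 or 4.

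Single mice lay apart from the 4 others of their genotype in 21 of 312 groups of 5 values, where chance gives about 15.6 at 1 in 20, with 11 among wild types and 10 among mutants. In mutant 5, Col14a1 read 8.78 (others 9.21 to 9.38), Cyp4b1 read 11.44 (others 11.86 to 12.01) and the mean of the distal nephron list was 6.85 (others 7.86 to 8.21). In mutant 4, Akap12 read 11.12 (others 11.36 to 11.42), Aqp3 read 7.08 (others 6.55 to 6.59) and the mean of the mitochondrial list was 12.08 (others 11.97 to 11.99). In mutant 1, Tnc read 9.36 (others 9.63 to 9.70), Aqr 9.33 (others 9.46 to 9.51) and Cpne1 11.56 (others 11.73 to 11.80), and in mutant 2, Cyp2s1 read 6.82 (others 6.51 to 6.59). Wild type 5 had higher Slc4a1 at 7.10 (others 6.58 to 6.69), Slc25a37 at 9.76 (others 9.13 to 9.29) and Hbb-b2 at 8.98 (others 7.42 to 7.87). Wild type 3 had Ctsl at 13.61 (others 13.16 to 13.26), Calr at 13.02 (others 13.47 to 13.61), Eif2s3y at 9.63 (others 8.98 to 9.16) and Ptch1 at 11.35 (others 11.13 to 11.18). Scand1 in wild type 1 read 11.18 (others 10.82 to 10.85), Nos3 in wild type 2 read 10.04 (others 9.72 to 9.80), and the mean of the mesangial list in wild type 4 was 10.39 (others 10.55 to 10.59).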

How the results depend on the processing

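The tubule score as a covariate (434 probe sets, 250 genes, 5 lists) and the chromosome 2 odds ratio leaving aside the genes from Cep250 to Rab5if (1.46, two-sided Fisher exact p = 0.0982) were chosen only after the data were seen. Of 135 named genes, 60 passed, and each kept its direction in every alternative that gave it a value. In the fits that left out 1 mouse, 40 to 52 of the 60 stayed past the threshold, 38 in all 10 and 22 lost in at least 1. Among wild types 2 to 4 and mutants 1 to 4, whose animal numbers lie close together, it was 29 of 60, and 28 with the number run as a block. Among genes that did not pass, 23 values changed sign without passing. Itga4, uncalled at -0.45, was the exception that changed sign and passed, and turned to 0.46 (adjusted p = 0.0179) with the mean of all probe sets of a gene, which takes in the raised probe set of Itga4.

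At an adjusted p under 0.01 there were 144 probe sets (56 higher, 88 lower) and 90 genes, fewer by construction, and the chromosome 2 odds ratio was 1.66 (two-sided Fisher exact p = 0.114). A 2-fold minimum gave 129 (71 higher, 58 lower) and 81 genes, also by construction, and an odds ratio of 1.49 (two-sided Fisher exact p = 0.292). Wild types 2 to 4 and mutants 1 to 4 gave 110 (58 higher, 52 lower) and 68 genes, and with the number run as a block 126 (70 higher, 56 lower) and 77 genes, with fewer mice in the fit. Leaving out 1 mouse gave 216 to 301 probe sets (78 to 140 higher, 137 to 172 lower), 133 to 190 genes, a chromosome 2 odds ratio of 1.47 to 2.64, a Wt1 change of 0.27 to 0.38 and 3 to 8 gene lists past the threshold. An estimated correlation gave 0 lists and fry's test of a shared direction gave 0. The cause of the changed list and chromosome 2 calls was not tested. Centring (354), quantile normalization (409) and the other settings kept the total within 1.5 times of 384, and camera has no robust option, so list values with trend and robust equal those with trend. Without probe sets ending in _s_at or _x_at (356 called) Wt1 had no value. No paired analysis was possible because replicate numbers follow accession order and litters are not given in the sources used here. Arrays give no counts, so weak signals near the floor limit the precision of low genes.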

Other observations

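The retinoid and Hedgehog lists, all their tests and the chromosome 2 test that leaves genes aside were chosen only after the calls were seen, and the retinoid and Hedgehog tests weighed here replaced a first version, a Fisher exact test over whole lists that held the genes which prompted them.

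Enzymes of retinoid metabolism moved in both directions. Cyp26a1 (3.35 ± 0.31 SE), the retinaldehyde dehydrogenase gene Aldh1a2 (1.74 ± 0.24 SE, adjusted p = 0.00588) and the retinol dehydrogenase gene Rdh10 (0.47 ± 0.09 SE, adjusted p = 0.0461) rose. Aldh1a1 fell by 1.06 ± 0.14 (SE, adjusted p = 0.00371) and Rdh9 fell by 0.82 ± 0.12 (SE, adjusted p = 0.00883). The Rdh10 call held only without mutant 2 when 1 mouse was left out (adjusted p up to 0.125 otherwise). Of 39 measured genes 5 passed, an odds ratio of 11.7 (95% interval 3.54 to 30.5, two-sided Fisher exact p = 0.000125, adjusted p = 0.000251), which is circular because the list was prompted by its called members. A coordinated change of this pathway may be proposed only as a hypothesis: among the 34 members that did not pass, 6 had an unadjusted p under 0.05, an odds ratio of 1.96 (0.663 to 4.84, two-sided Fisher exact p = 0.142), which leaves it open.

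Among 27 measured Hedgehog genes, 3 passed and all fell: the co-receptor gene Cdon by 2.07, the signal transducer gene Smo by 0.63 ± 0.08 (SE, adjusted p = 0.00454) and the ligand release gene Disp1 by 0.51 ± 0.09 (SE, adjusted p = 0.0188), the last lost without wild type 1 or 5 (adjusted p up to 0.0556). The receptor gene Ptch1 changed by -0.48 (adjusted p = 0.0643) and Gpc3 by 0.84 (adjusted p = 0.0717). Over the whole list the odds ratio was 9.87 (95% interval 1.89 to 32.9, two-sided Fisher exact p = 0.00466), with the same circularity. A coordinated change may be proposed only as a hypothesis, since 3 of the 24 members that did not pass had an unadjusted p under 0.05, an odds ratio of 1.31 (0.249 to 4.38, two-sided Fisher exact p = 0.726).

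Chromosome 2 outside 30 Mb of Wt1 held 20 called genes of 953 tested, an odds ratio of 1.72 (1.03 to 2.74, two-sided Fisher exact p = 0.0256). Leaving aside the genes from Cep250 to Rab5if, chosen after seeing the data, it held 14 of 932, an odds ratio of 1.22 (0.656 to 2.11, two-sided Fisher exact p = 0.446).

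Probe sets of Itga4, an integrin gene chosen after its values were seen, disagreed. Itga4 probe set 1436037_at rose by 2.40 ± 0.13 (SE) with the smallest p of all probe sets (9.82e-10), and the one with the highest mean, 1450155_at, changed by -0.45 ± 0.16 (SE, adjusted p = 0.351). Other Itga4 probe sets changed by -0.58, 1.07 and -0.13, none past the threshold. A sequence variant under the probes was not tested for Itga4, because that test took only genes whose probe set with the highest mean was called. The counts of called genes on chromosome 2 and within 30 Mb of Wt1 also took only that probe set of each gene. They therefore cannot count the raised probe set of Itga4, and an effect of linked donor sequence on Itga4 was not tested.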
